A study of Drosophila melanogaster with 6 samples.

How the data were processed

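AGO2 ChIP-seq peaks were analysed for the S2 and the S3 line, each from 1 library made with antibody 9D6. The series holds 6 samples: 3 AGO2 ChIP libraries and 3 input libraries. Groups were taken from the sample titles. The S2 ChIP with the other antibody and the input libraries were not analysed here, so no background from input is given beside the peaks.

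The submitters' processing notes name Bowtie 0.12.5, MACS 1.3.7.1 and build dm3, without saying what each was used for. The authors deposited the lists of peaks used here separately for each of the 9D6 libraries, not pooled, and the track lines in the file headers name peaks at an FDR of 5%. Each deposited row gives a chromosome, a start, an end and a value read here as the FDR in percent; that reading rests on the track line and on the values, which reach 4.94 in S2 and 5 in S3. Which input library served as background, the filters on reads and the read depth are not given in the sources used here. Peak heights, fold enrichments and summits were not used here. The lists hold peaks on 2L, 2R, 3L, 3R, 4 and X. The FDR took 146 different values in S2 and 148 in S3, with many ties, and its smallest value above 0 was 0.07% and 0.06%, so it ranks peaks only coarsely. An FDR depends on the depth and background of its own library, and values from both lists are not on 1 scale. A peak caller draws borders from local read density, so a deeper library can give more, wider or differently divided peaks from the same binding.

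All further steps were done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Random placement moved each peak of a list to a random position on its own chromosome, keeping widths and without overlap within the list, 1000 times, with the other list fixed; the 2 rules that require an overlap of 50% were run with 100 placements. The span of a chromosome was taken as the largest peak end in either list. Placement over whole chromosomes ignores sequence that reads cannot be mapped to, so shifts of a list by 5 to 100 kb were added as a nearer background. Differences in median FDR and width between shared and line-specific peaks were tested with 100000 permutations of the peaks within a list, two-sided. Correlations across shared peaks had permutation p-values from 100000 permutations. Shares have exact binomial (Clopper-Pearson) intervals, counts have exact Poisson intervals, and differences between shares have Newcombe intervals, all at 95%. Density ratios of X to 2L, 2R, 3L and 3R have intervals from 20000 resamplings of 1 Mb bins. Since there is 1 library per line, p-values describe peaks within these lists and not the cell lines.

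The peaks named were fixed by a rule written before the data were examined: the 10 strongest peaks of each of 3 sets (shared, S2 only, S3 only) and the 3 windows of 100 kb with the most peaks in each line. Strength was the lowest FDR, and the many ties at 0 were broken by width, a detail added after the ties were seen. The rule also named genes near these peaks, members of fixed lists of homeotic, insulator, small RNA, Polycomb and other genes, and motifs. These parts, and the planned shares of peaks at promoters, exons and introns, were not carried out, since no genome or annotation of dm3 was used here and the gene table at hand belongs to another assembly. The alternatives tried were other overlap rules, the 50% of each list with the lower FDR (ties at the cut broken by width, the widest first), equal numbers of peaks, joined neighbouring peaks and circular shifts. The overlap code was checked on simulated lists of the same size: all 1000 sites planted among 2084 peaks were recovered, and 2 of 100 independent placements were called at 0.05. Planted sites were copies of S3 peaks and the other intervals were chosen to miss S3, so full recovery checks the code only. The independent placements came from the same procedure as the background. They lacked the clustering of the lists, so they do not show how the test behaves on clustered peaks.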

Results

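The data describe where Argonaute 2 (AGO2), the Argonaute protein of the small interfering RNA pathway, was found on chromatin in a pair of Drosophila melanogaster cell lines. S2 and S3 are Schneider's lines, which were established from embryos. The series is about a role of AGO2 at chromatin insulators bound by CTCF and CP190, and its stated design sets the S2 line beside the S3 line. Chromatin immunoprecipitation with the monoclonal anti-AGO2 antibody 9D6, followed by sequencing (ChIP-seq), gave 1 list of peaks per line. An S2 ChIP with another AGO2 antibody and 3 input libraries belong to the series as well; their values were not analysed here. Each line is therefore represented by 1 library, so no value below has a replicate error and no test compares the lines themselves. Read depth is unknown, and no interval covers variation between libraries. Positions are given on build dm3, counted from 1. No gene annotation of that build was used, so peaks are named by position and not by gene.

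The first comparison asked how much of the genome AGO2 occupied in each line. The S3 list held 3159 peaks (95% exact Poisson interval 3049.8 to 3271.1) and the S2 list 2084 (1995.5 to 2175.4), a ratio of 1.52 (exact conditional interval 1.43 to 1.60). The interval of the ratio treats the lists as independent counts, although many sites were in both. S3 peaks covered 5.44 Mb and S2 peaks 3.25 Mb, which is 4.56% and 2.73% of the 119.3 Mb spanned by the peaks of both lists. Peaks were also broader in S3, with a median width of 1358 bp (quartiles 880 and 2145) against 1194 bp (779.8 and 1862) in S2. Peaks of 5 kb or more numbered 94 in S3 and 48 in S2. The authors' false discovery rate (FDR), the only strength given for a peak, was listed at 0 for 48.5% of S3 peaks (46.7 to 50.2%) and for 23.3% of S2 peaks (21.5 to 25.1%). Among peaks at an FDR of 0, the S3 list was 3.16 times as long as the S2 list, although the FDR values of the lists are not on 1 scale.

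The second comparison asked whether the AGO2 peaks of both lists lay at the same places. Most S2 sites were also S3 sites: 1786 of 2084 S2 peaks (85.7%, exact binomial interval 84.1 to 87.2%) overlapped an S3 peak by at least 1 bp. In the other direction, 1752 of 3159 S3 peaks (55.5%, 53.7 to 57.2%) overlapped an S2 peak, which left 298 peaks found in S2 alone and 1407 found in S3 alone. Random placement of the S2 peaks within their chromosomes gave 165.4 overlapping peaks on average and at most 200, so the observed number was 10.8 times higher. The same ratio for S3 peaks was 10.6. In both directions p was 0.001, the smallest that 1000 placements can give. The peaks at an FDR of 0 numbered 485 in S2 and 1531 in S3. With only these peaks in both lists, 94.0% of S2 peaks and 30.2% of S3 peaks were shared. The shorter S2 list limits the S3 share in this setting, and to a lesser degree in the main one. With equal numbers of peaks in both lists the shares were 72.5% and 69.5%.

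The coincidence was one of peak positions and not only of broad regions. Both lists come from the same antibody, and the input libraries and the other antibody were not analysed. Random placement and shifts cannot separate AGO2 binding from other signal common to both libraries, so the source of the coincidence was not tested. Moving the S2 list by 5 kb lowered the share of overlapping peaks from 85.7% to 19.4%, and moving it by 100 kb lowered it to 7.63%. The observed number of shared S2 peaks was 4.42 times that after a shift of 5 kb, a smaller ratio than against random placement. In the 1490 pairs with 1 partner each, the centres of the S2 and the S3 peak lay a median of 88 bp apart (quartiles 26 and 358.8 bp). The S3 peak was the wider one in 984 of these pairs (66.0%, 63.6 to 68.4%), and its width was a median of 1.055 times that of its S2 partner. The S2 peak lay entirely inside the S3 peak in 608 pairs. In all, 75.7% of the sequence covered by S2 peaks lay inside S3 peaks, and 45.3% of that covered by S3 peaks lay inside S2 peaks.

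**Figure D1:**
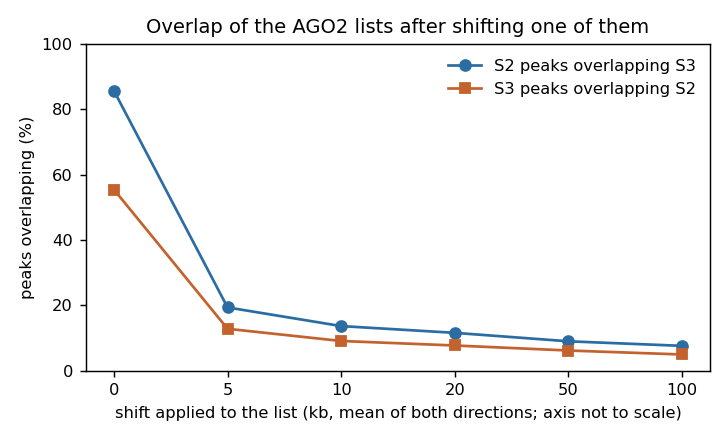
Percent of S2 peaks overlapping an S3 peak (blue circles) and of S3 peaks overlapping an S2 peak (orange squares), on the vertical axis, after moving the list by the number of kb on the horizontal axis, as the mean of both directions. The shares fell from 85.7% and 55.5% without a shift to 19.4% and 12.9% at 5 kb.

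The 10 named shared regions, ranked by FDR and then by width in S2, were 5272 to 15202 bp wide, and 5 of them lay on 3R, 2 on 2R and 1 each on 2L, 3L and X. On 2R, the S2 peak at positions 7475833 to 7482262 met an S3 peak at 7475838 to 7482251, so that both lists drew nearly the same borders around a region of 6430 bp in S2 and 6414 bp in S3. On 2L, an S2 peak of 7382 bp from 19570141 to 19577522 likewise met an S3 peak of 7281 bp. The broadest region differed in form: on 3R, a single S2 peak of 15202 bp from 3938399 to 3953600 faced 3 separate S3 peaks, of which the widest measured 1388 bp. All 10 were listed at an FDR of 0 in S2, and each had at least 1 S3 partner at an FDR of 0.

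Sites found in one line alone had a higher FDR and were narrower than shared sites. In S2 the median FDR was 0.61% for the 298 S2-only peaks and 0.11% for the 1786 shared peaks; in S3 it was 0.16% for S3-only peaks and 0 for shared peaks. Both differences had an adjusted p of 1e-05, the smallest that 100000 permutations of the peaks can give (two-sided permutation test of medians, Benjamini-Hochberg over 4 tests). Shared peaks were wider than line-specific ones by a median of 240 bp in S3 (1462 against 1222 bp, adjusted permutation p = 1e-05) and 148.5 bp in S2 (1217.5 against 1069 bp, adjusted p = 0.011). These tests treat peaks within a library as the unit. Under a rule of 1 bp a wider peak also meets the other list more often by position alone. The permutation does not allow for that, so part of the width difference can follow from the rule.

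The share of common sites fell as the FDR rose in both lists. Of the 485 S2 peaks at an FDR of 0, 476 (98.1%, 96.5 to 99.2%) had an S3 partner, and 66.5% (61.5 to 71.2%) of the 382 S2 peaks with an FDR above 1% had one. In S3, 79.6% (77.4 to 81.5%) of the 1531 peaks at an FDR of 0 and 22.8% (18.7 to 27.4%) of the 377 peaks above 1% had an S2 partner. The remaining 313 S3 peaks at an FDR of 0 had no S2 partner, and 9 S2 peaks at an FDR of 0 had no S3 partner. These counts cannot be set against each other, since the FDR values are not on 1 scale and the lists differ in length. The share of S3 peaks with a partner was 46.3% (42.4 to 50.3%) among the narrowest 20% of peaks and 64.3% (60.5 to 68.1%) among the widest 20%, against 3.66% and 7.81% after random placement. In S2 it was 79.6% (75.4 to 83.4%) among the narrowest 20% and between 86.3% and 88.7% in the other 4 width classes, where random placement gave 5.77% for the narrowest and 11.7% for the widest class.

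**Figure D2:**
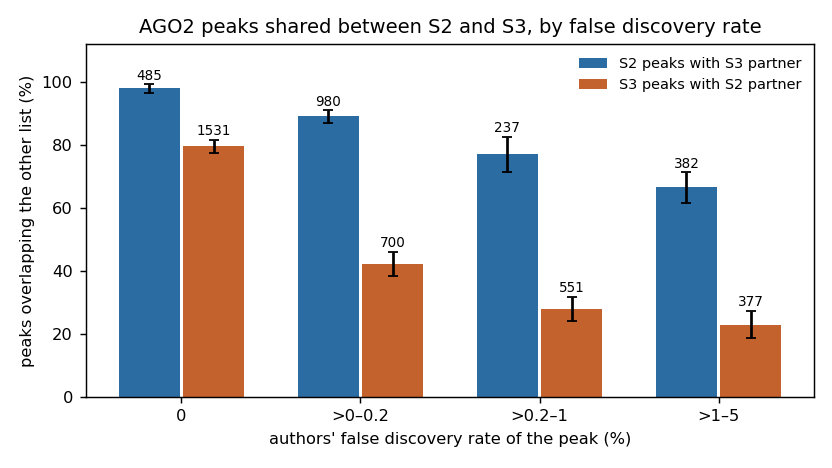
Percent of peaks that overlap a peak of the other line (vertical axis) in 4 classes of the authors' false discovery rate in percent (horizontal axis), for S2 peaks (blue) and S3 peaks (orange). Error bars are 95% exact binomial intervals and the count on each bar is its number of peaks; the share falls from 98.1% to 66.5% in S2 and from 79.6% to 22.8% in S3.

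S3-specific sites with the lowest FDR lay on all of the large arms. The 10 named S3-only peaks were all listed at an FDR of 0 and measured 3955 to 5296 bp, 3 of them on X, 2 each on 2R, 3L and 3R, and 1 on 2L. The broadest, on X from 545648 to 550943, was 29.7 kb from the nearest S2 peak. Another on 2R, from 11839323 to 11844150, had no S2 peak within 87.7 kb, and one on 3L, from 878053 to 882525, had none within 101.6 kb. The 10 named S2-only sites, which took in all 9 S2-only peaks at an FDR of 0 and 1 at 0.07%, measured 592 to 4989 bp, and none lay on X. Since the 10 S3-only sites were the widest of 313 at an FDR of 0, the widths of the named sets cannot be set against each other. The broadest of them, on 3L from 2531342 to 2536330, was 16.2 kb from the nearest S3 peak. Others were near misses: the S2-only peak on 2L from 470022 to 471303 was separated from an S3 peak by 1 bp. Of all line-specific peaks, 34.6% in S2 and 28.8% in S3 lay within 5 kb of a peak of the other line, against 18.3% and 12.8% after random placement (permutation of positions, p = 0.001 for both, the smallest that 1000 placements can give).

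At shared sites the broad peaks of one line tended to be broad in the other. Across 1786 shared S2 peaks, each taken with its S3 partner of lowest FDR, widths had a Spearman rho of 0.58 and a Pearson r of 0.53. The FDR values had a rho of 0.33 and an r of 0.21. Of the 1752 shared S3 peaks, 1218 were tied at an FDR of 0, and partners were picked by FDR. The values for FDR therefore cannot be set against those for width. These 4 correlations had an adjusted permutation p of 1e-05, the smallest possible. In the pairs with 1 partner each, rho was 0.71 for width and 0.35 for FDR. All are correlations across peaks of a pair of libraries, and peaks are not independent replicates.

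The third comparison concerned the chromosome arms. The X chromosome held the densest set of AGO2 peaks in both lines, at 21.7 peaks per Mb in S2 and 35.3 in S3, against 16.6 and 24.6 on 2L, 2R, 3L and 3R together. The ratio of X to autosomal density was 1.31 in S2 (1.08 to 1.56, 95% interval from resampling 1 Mb bins) and 1.43 in S3 (1.24 to 1.63). Bins of 1 Mb on X held a median of 21 S2 peaks against 16 in autosomal bins (permutation test over 22 and 94 bins, adjusted p = 0.027) and 37.5 S3 peaks against 25.5 (adjusted p = 8e-05). X peaks were narrower, however, with a median of 913 bp against 1268 bp on the autosomes in S2 and 1018.5 bp against 1470.5 bp in S3 (permutation p = 1e-05 in each). The length covered per Mb of X was therefore 1.01 times that of the autosomes in S2 and 0.99 times in S3. In the 50% of each list with the lower FDR, the density ratio was 1.12 (0.85 to 1.45) in S2 and 1.23 (0.995 to 1.48) in S3, and both intervals included 1. Among peaks at an FDR of 0 it was 1.05 (0.65 to 1.54) in S2, and 1.24 in S3 with an interval of 1.005 to 1.496 that excluded 1 narrowly. Among line-specific peaks the ratio was 0.99 (0.73 to 1.28) in S2, with 55 of 298 peaks on X, and 1.49 (1.27 to 1.72) in S3, with 363 of 1407 on X.

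The division of peaks over the arms was close in both lists. X carried 23.3% of S2 peaks and 25.01% of S3 peaks, a difference of 1.74 percentage points with a 95% interval from -0.64 to 4.08. That interval treats the lists as independent and ignores that most S2 peaks overlapped an S3 peak. The corresponding intervals for 2L, 2R, 3L, 3R and the small chromosome 4 also included 0. Chromosome 4 had the lowest density, with 12 S2 peaks and 13 S3 peaks, or 9.15 and 9.92 per Mb. The X to autosome ratio of S3 divided by that of S2 was 1.10 (0.998 to 1.21), an interval that included 1. After joining peaks closer than 500 bp it was 1.12 (1.04 to 1.22), an interval that excluded 1, so the result depended on joining.

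**Figure D3:**
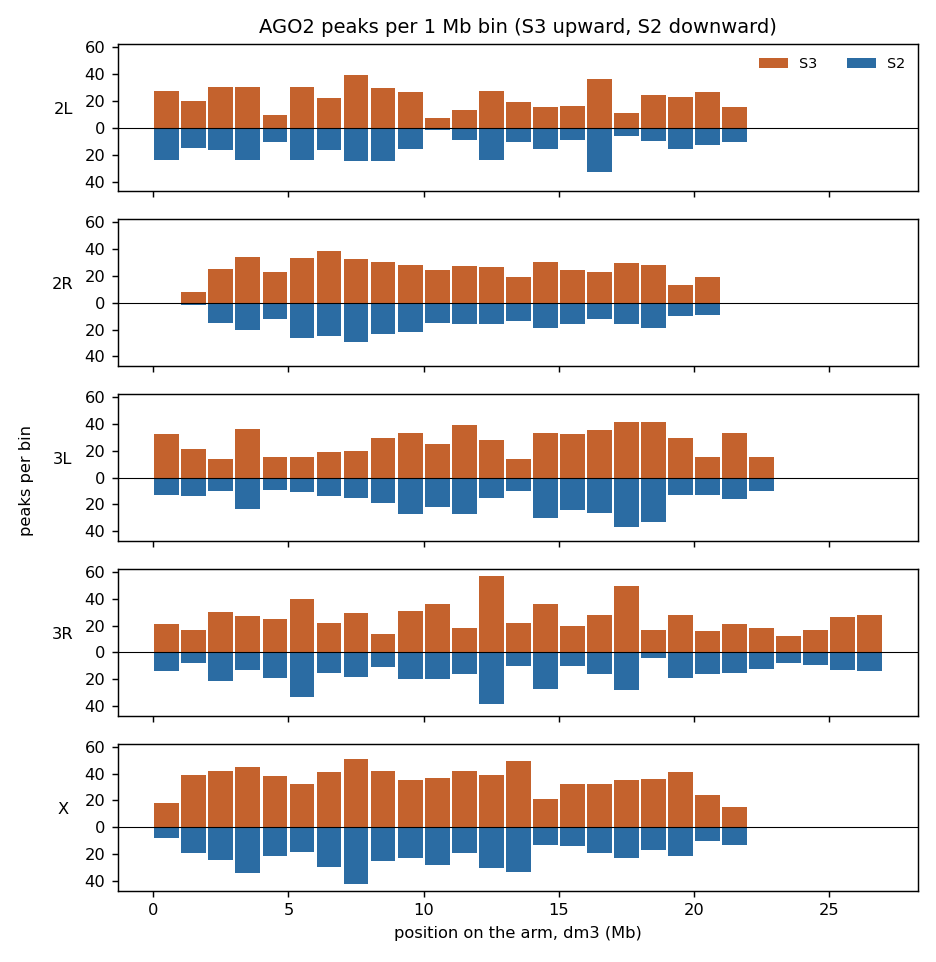
Number of AGO2 peaks per full 1 Mb bin (vertical axis) along the 5 large arms on dm3 (horizontal axis, Mb), with S3 drawn upward in orange and S2 downward in blue. Dense and sparse bins fall at like positions in both lists, and the highest bins hold 57 S3 peaks and 42 S2 peaks.

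AGO2 peaks lay in clusters along the arms. The median gap to the nearest peak of the same list was 5.62 kb in S2 and 3.85 kb in S3, or 0.29 and 0.31 times that of random placement (permutation of positions, p = 0.001 for both, the smallest possible). After joining peaks closer than 500 bp, these ratios were 0.59 and 0.58, with the same p. Random placement also used sequence that reads cannot be mapped to, and shifting a list does not change its own gaps. Part of the clustering can therefore follow from where reads can be mapped. The 100 kb window from 3.6 to 3.7 Mb on X held the most S2 peaks, 14, with 13 in S3. The windows at 12 to 12.1 Mb on 3R and 7.5 to 7.6 Mb on X followed, with 13 S2 peaks each, and with 13 and 12 S3 peaks. S3 peaks were most frequent at 17.4 to 17.5 Mb on 3R, where 16 were listed against 11 in S2. Random placement of the peaks as listed gave at most 12 S2 peaks and at most 14 S3 peaks in any window. The largest window count averaged 7.35 in S2 and 9.41 in S3. Window maxima were not recomputed for joined peaks, so the lower joined counts given below have no such background. Whether these windows exceed random placement after joining was not tested.

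The next densest S3 windows held 14 S3 peaks each. Between 12.7 and 12.8 Mb on 3R, 14 peaks were listed in S3 and 7 in S2; all 7 S2 peaks had an S3 partner, and 6 of the 14 S3 peaks had an S2 partner. The other window, at 12.6 to 12.7 Mb on X, held 14 S3 and 12 S2 peaks. Joining peaks closer than 500 bp left 12 S3 and 6 S2 peaks in the 3R window at 12.7 Mb, but only 7 S3 and 6 S2 peaks in the X window at 12.6 Mb. An S3 excess of 6 was not unusual, since the largest excess in any window had a median of 7 when shared and line-specific labels were permuted over joined sites within arms. Joining left 7 S2 and 8 S3 peaks in the X window at 3.6 Mb, 4 and 7 in the 3R window at 12 Mb, 7 and 6 in the X window at 7.5 Mb, and 8 and 9 in the 3R window at 17.4 Mb.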

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

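What drew attention here was the size of the gap in median FDR between shared and line-specific peaks in each list, a comparison chosen after the data were seen. Shared peaks had a lower median FDR than line-specific peaks by 0.5 percentage points in S2 (0.11% against 0.61%) and by 0.16 in S3 (0 against 0.16%). The S3 difference minus the S2 difference was 0.34 percentage points, with a 95% interval of 0.08 to 0.67 from resampling the peaks. Each FDR is relative to the background of its own library, so these gaps have no common scale, and with 1 library per line the interval does not show that the lines differ. Of the 1752 shared S3 peaks, 1218 were at an FDR of 0, the lowest value a list can hold, so their median could not be lower. The smaller S3 gap went with a lower median FDR of line-specific peaks, 0.16% in S3 against 0.61% in S2. For width, the S3 difference minus the S2 difference was 91.5 bp, with an interval from -29.0 to 222.5 bp that included 0.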

How the results depend on the processing

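The shifts by 5 to 100 kb, the restriction to peaks at an FDR of 0, the joining of peaks for the X to autosome ratio and the background by width were chosen after seeing the data. Of 113 values recomputed under alternatives, 86 were counted as kept, by rules that differed between results. Tested results had to keep their direction and side of the threshold. Median widths, arm shares and the ratio of peak numbers had to stay within their spread, and counts within a fixed factor. Overlap settings other than the shifts were counted both as a share and as a fold, and both were judged by the fold. An S3 share of 30.2%, against 55.5% in the main setting, therefore counted as kept. The excess of shared peaks over background held in every setting run: the fold ranged from 8.79 to 36.7 in S2 and from 9.09 to 36.7 in S3 over the overlap, length, FDR, circular-shift and joining alternatives, and was lowest, at 4.42 and 4.32, against a shift of 5 kb. The highest fold, with an overlap of 50% of each peak, rests on 100 random placements only. The shares ranged from 64.6% to 94.0% of S2 peaks and from 30.2% to 69.5% of S3 peaks. Requiring an overlap of 50% of each peak gave the lowest S2 share, and the peaks at an FDR of 0 gave the lowest S3 share. That setting put 1531 S3 peaks beside 485 S2 peaks, which by itself limits the S3 share. Against the full S2 list, 79.6% of these S3 peaks were shared.

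In the 50% of each list with the lower FDR, the X to autosome ratio fell to 1.12 (0.85 to 1.45) in S2 and 1.23 (0.995 to 1.48) in S3, and both intervals included 1. In S3 that depended on where the list was cut: the cut took in the 1531 peaks at an FDR of 0 and added the widest of the next ties to reach 1579, while the peaks at an FDR of 0 alone gave 1.24 (1.005 to 1.496), which kept the call narrowly. In S2 the peaks at an FDR of 0 gave 1.05 (0.65 to 1.54). Among line-specific peaks it was 0.99 in S2, on the other side of 1, with an interval of 0.73 to 1.28 over 55 X peaks, and 1.49 in S3 (1.27 to 1.72, 363 X peaks); the cause was not tested. The lists shortened to the lower FDR held 1042 S2 and 1579 S3 peaks by construction, with median widths of 1242.5 and 1510 bp, and joining peaks closer than 500 bp widened the medians to 1417 and 1602.5 bp by construction. The S3 to S2 ratio of peak numbers was 3.16 among peaks at an FDR of 0. The planned setting without the separate heterochromatic and unplaced sequences of the build was void, since neither list holds peaks on them, and the settings for genes, features and motifs were not run. No paired analysis was possible because each line has 1 library with a list. Without read depths, a site missing from a list was below the authors' threshold in that library, which does not show that AGO2 was absent.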

Other observations

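The tests of S2 sensitivity, of the split region on 3L and of windows without an S2 peak, the density ratios by FDR class and the counts next to centromeres were chosen after the results were seen. Both lists were sparse beside the centromeres of some arms. The 1 Mb of each arm nearest its centromere (the end of 2L, 3L and X and the start of 2R and 3R, up to the last listed peak) held 32 S2 peaks and 59 S3 peaks over 5 arms, or 6.4 and 11.8 per Mb, against medians of 16 and 27 over all full 1 Mb bins. On 2R this stretch held 1 S2 peak and 0 S3 peaks. On 3L it held 1 S2 peak and 12 S3 peaks. Of these S3 peaks, 9 lay within 4.55 kb and were left as 2 after joining peaks closer than 500 bp, so they raise the S3 total. On 3R it held 14 and 21, near the arm's medians of 15 and 25. On X it held 7 and 11, against the arm's medians of 21 and 37.5. On 2L it held 9 and 15, against 16 and 23.5. The median over the 5 stretches was 7 in S2 and 12 in S3. Mappability was not analysed here, so sequence that reads cannot be mapped to is not excluded as the reason. Across 116 full bins of the 5 large arms, S2 and S3 counts had a Pearson r of 0.87 and a Spearman rho of 0.87 (permutation p = 1e-05, the smallest possible). Bins are not independent samples. Since 85.7% of S2 peaks overlapped an S3 peak, the same sites enter both counts, so this correlation adds little to the overlap.

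The S3 list was longer than the S2 list, and 1407 of its peaks had no S2 partner. A lower sensitivity of the S2 library stays open as a candidate explanation, and no value here decides it: the share of S3 peaks without a partner was higher above an FDR of 1% than at 0 by 56.8 percentage points (77.2% against 20.4%), but the S2 list showed the same direction (33.5% against 1.86%), where low S2 sensitivity cannot be the reason. Differences in copy number between the lines are another candidate explanation, which the test run cannot tell from other causes. The S3-only share varied between 1 Mb bins more than in most permutations of the labels within arms. The mean squared deviation was 1.42 against a permuted median of 0.95 and a highest of 1.465 (permutation p = 0.001). After joining, it was 1.24 against a highest of 1.597 (permutation p = 0.014). The permutation did not hold the FDR or width of peaks fixed, although the share varied with both. It also treated neighbouring peaks as independent, although peaks lay in clusters. Bins whose peaks differ in these respects could vary without any difference in copy number. Among the 85 bins with at least 20 S3 peaks that share ranged from 18.5% at 12 to 13 Mb on 2L to 71.9% at 15 to 16 Mb on X. These are the extremes of many bins with few peaks each, and no expected range was computed for them. The bins beside the latter, at 14 to 15 and 16 to 17 Mb on X, had 42.9% and 43.8%. Variation between bins would also follow from regions that differ in AGO2 binding between the lines, and that biological difference stays open and untested.

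Peaks were denser on X than on the autosomal arms in both lists. Joining peaks closer than 500 bp left the X to autosome ratio at 1.25 in S2 (1.07 to 1.44) and 1.40 in S3 (1.22 to 1.58), which argues against the splitting of X regions into peaks closer than 500 bp as the whole cause. Pieces further apart were not joined, so splitting over longer distances stays open. X peaks were narrower, and the length covered per Mb of X was 1.01 and 0.99 times that of the autosomes in S2 and S3. Weak peaks near the threshold stay open as a candidate explanation, and no value here decides it: in the 50% of each list with the lower FDR the ratio was 1.12 (0.85 to 1.45) in S2 and 1.23 (0.995 to 1.48) in S3, but among S3 peaks at an FDR of 0 its interval excluded 1 narrowly, and shortening the lists also widened the intervals. By class, the ratio rose from 1.05 (0.65 to 1.54) at an FDR of 0 to 1.80 (1.40 to 2.27) above 1% in S2 and from 1.24 (1.005 to 1.496) to 1.78 (1.37 to 2.27) in S3. The copy number of X and its coverage in the input were not analysed here, and no biological explanation was tested.

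A pair of 100 kb windows held 8 or more S3 peaks and no S2 peak. On 3L, 9 S3 peaks with a median width of 341 bp lay within 4.55 kb, from 24531193 to 24535741, at the last listed position of the arm; joining peaks closer than 500 bp left 2, but with a mean gap of 196.5 bp between them most had to join, so this does not test whether 1 region was divided into many peaks, and that stays open. On X, 8 S3 peaks with a median width of 1295 bp stood between 15342181 and 15396495, and 7 remained after joining. In 5000 permutations of shared and line-specific labels over sites within arms, 6.46% gave some window with 7 or more S3 peaks and no S2 peak, so uneven scatter of S3-only sites is not excluded as the reason, although most permutations gave no such window. An S3 excess of 7 or more in some window arose in 58.8%, but that count includes windows with S2 peaks and does not decide the matter. Whether this stretch of X differs between the lines in copy number or in binding stays open.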
